A study of Homo sapiens with 51 samples.

How the data were processed

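The submitters' processing notes list cutadapt 1.5, STAR 2.5.2a, RSEM 1.3.0 and GRCh38, and the deposited table holds whole-number counts for 58051 gene rows in 51 libraries. The notes name the tools without their roles, and the annotation release, the strand setting and any filter are not stated. Whether the values are read counts or rounded RSEM estimates, in which reads that fit several genes are divided, is not stated, and this bears on ratios over 1 to 3 counts and on near-identical genes. The values were used here as counts. All 51 columns were matched to samples and 0 columns belonged to no sample. A symbol was given for 56948 rows (98.1%), which held 99.8% of the counts, and 41229 rows had at least 1 count.

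Counts were analysed with edgeR 4.0.16 in R 4.3.3. Low counts were filtered with filterByExpr over the 17 groups (minimum count 10, minimum total 15), which kept 19603 genes with 99.95% of all counts, 19343 of them with a symbol. Libraries were scaled by trimmed mean of M values (TMM) factors, which ran from 0.966 to 1.03. Negative binomial models with 1 mean per group were fitted to the 51 libraries at once (common dispersion 0.0038), and contrasts were tested with the quasi-likelihood F test. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 within the comparison and a log2 fold change of at least 1 in either direction. There were 25 comparisons: BMP4 versus Activin+BMP4 at 8 times, each condition versus untreated at 8 times, and the change of the former between 24 h and 96 h. Log2 fold changes carry a standard error. With 0 counts in a group the change is given as a lower bound with a floor of 3 counts over the group, and with 1 to 3 counts as a ratio with a 95% interval for counting error. Principal components were taken from log2 CPM of the 2000 most variable genes.

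The rule for named genes was fixed before the data were examined. For BMP4 versus Activin+BMP4 at 6, 24, 48 and 96 h it took the 6 highest and 6 lowest log2 fold changes among called genes with at least 10 CPM in the higher group, no overlap between the 3 libraries on each side and no clone-type symbol. It took 4 and 4 for each condition versus untreated at 24 and 96 h and for the comparisons at 1 h, and 5 and 5 for the interaction, where the conditions were not to overlap at 96 h. Genes of the fate panel were open to naming at any time, as were up to 4 called members of each described list. Some genes that the rule takes are not reported here.

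In all, 23 gene lists and a fate panel of 28 genes were fixed at the same stage. They are pluripotency, primitive streak, definitive endoderm, visceral and yolk sac endoderm, nascent and paraxial mesoderm, lateral plate and extraembryonic mesoderm, amnion, trophoblast, primordial germ cell, neural ectoderm, endothelial and blood, HOX, Activin and NODAL target, BMP target, WNT target, epithelial, mesenchymal and migration, cell cycle, immediate early, p53 target and apoptosis, hypoxia and glycolysis, cholesterol synthesis and mitochondrially encoded genes. Each was tested with camera from limma 3.58.1 in 9 comparisons, with a preset correlation between genes of 0.01 and Benjamini-Hochberg adjustment over the 216 tests, and again with a correlation estimated from the data. With the preset correlation 107 of the 216 tests were called, and with the estimated one 75. List members were also adjusted over the list alone. Counts are over the members that passed the filter, which left out 13 of 26 trophoblast and 16 of 39 HOX genes, so members of such lists were tested because they were expressed in some group. Lists share members, so their results are not independent: 9 of 17 Activin and NODAL targets, 8 of 18 primitive streak, 8 of 20 amnion and 7 of 17 BMP target genes are in another list too.

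In a test with made-up changes, counts of 19603 genes were simulated with equal means in all groups and a single shared dispersion. Genes were drawn independently. In the BMP4 96 h libraries 200 genes were changed, picked from those above a minimum expected count. Of 67 genes changed 1.5-fold 1.5% were called, of 67 changed 3-fold and 66 changed 8-fold 100% were called, and of 19403 unchanged genes 0.01%. The 1.5-fold change lies below the 2-fold threshold, so few such calls were possible. Genes with low counts or a wider spread were not tried. A raised list had a camera p of 4.34e-179, or 1.01e-26 with an estimated correlation, and 0 of 20 unchanged lists were called. As the simulated genes were independent, this cannot test the preset correlation.

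Counts of called genes and named genes were computed again with relative log expression (RLE) factors, without scaling factors, without the filter, with a stricter filter (at least 1 CPM in 3 libraries and on average), with DESeq2 1.42.0, with only the groups compared in the fit, with replicate number as a block and with each library left out in turn. The list tests were computed again only with an estimated correlation and with the block. A fit without the 3 libraries that stood apart was added after the results were seen. Replicate numbers did not pair the libraries: over 408 pairs of libraries with the same number in different groups the median correlation of deviations from the group mean was 0.0036 (-0.39 to 0.51). Of the 51 libraries, 19 matched best to a library of their own number. No 2 replicates were identical. Gene positions are from GENCODE v29 on GRCh38. Because the strand setting of the counts is not given, genes that overlap others are uncertain. They are 44 of the 97 named and panel genes with a location, and not each is marked below. LEFTY1, LEFTY2, LGR5 and HOXB9 are among them, each with an overlap on the same strand.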

Results

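H1, an established human embryonic stem cell line, was sampled before treatment and at 8 times up to 96 h after the growth factors were added. In one condition the cells received Activin at 100 ng/mL together with BMP4 at 10 ng/mL, and in the other they received BMP4 alone at 50 ng/mL. Activin signals through the same receptors as NODAL, and both ligands are used to drive pluripotent cells towards the lineages of the gastrula. The 51 libraries formed 17 groups of 3. The labels give total RNA as the extracted molecule and mRNA in the description of the design, and name no enrichment step, so values of small noncoding and histone genes are uncertain. Totals ran from 22.8 M to 30.4 M counts per library with a median of 24.9 M. Levels are CPM, counts scaled to library totals adjusted by the scaling factors, given as mean ± SD with n = 3 libraries per group. The labels give replicate numbers but name no separate cultures, so p-values measure the spread between these samples. A gene was called when edgeR's quasi-likelihood test gave a Benjamini-Hochberg adjusted p under 0.05 and the change was at least 2-fold. The conditions differed in both Activin and BMP4 dose, and treated cells also left the maintenance medium for one with insulin, FGF2 and a compound that the labels write as LY29004, so neither factor has a comparison of its own here.

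The number of genes that differed between BMP4 and Activin+BMP4 rose from 1 at 1 h to 100 at 6 h, 279 at 12 h, 795 at 24 h, 1114 at 36 h, 1851 at 48 h, 1955 at 72 h and 3098 at 96 h, out of 19603 tested. The first principal component held 44.6% of the variance among the 2000 most variable genes and followed time in both conditions. The second held 15.8% and separated the conditions without overlap at every time, by little at 1 and 6 h and more widely from 24 h on. Among replicates the lowest correlation of log2 CPM was 0.9847. In 3 groups 1 library stood apart, with a chi-square per degree of freedom (a squared distance) to each of the other 2 at least 3 times that between those 2. These were Activin+BMP4 48 h replicate 2, Activin+BMP4 96 h replicate 3 and BMP4 12 h replicate 1. The share of counts on mitochondrially encoded genes was 2.46% ± 0.256 in untreated cells, 0.81% ± 0.176 at 72 h and 1.5% ± 0.329 at 96 h with Activin+BMP4, and 1.1% ± 0.35 and 1.17% ± 0.418 at those times with BMP4.

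**Figure D1:**
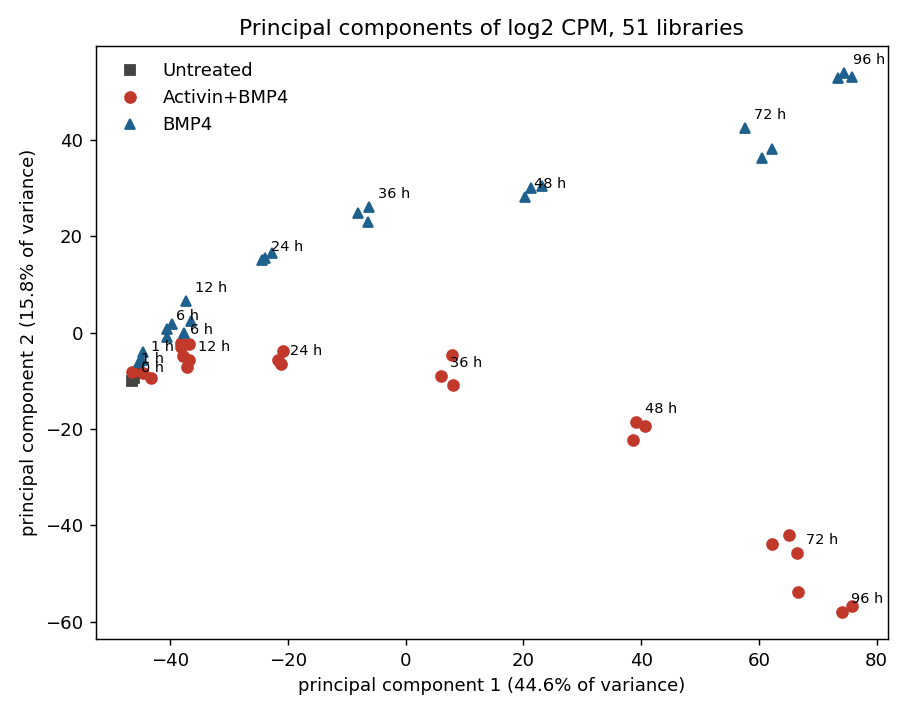
Scores of the 51 libraries on principal component 1 (44.6% of variance) and principal component 2 (15.8%), with squares for untreated, circles for Activin+BMP4 and triangles for BMP4 libraries, and the time in hours beside replicate 1 of each group. The conditions lie close at 1 h and far apart on the vertical axis at 96 h.

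**Figure D2:**
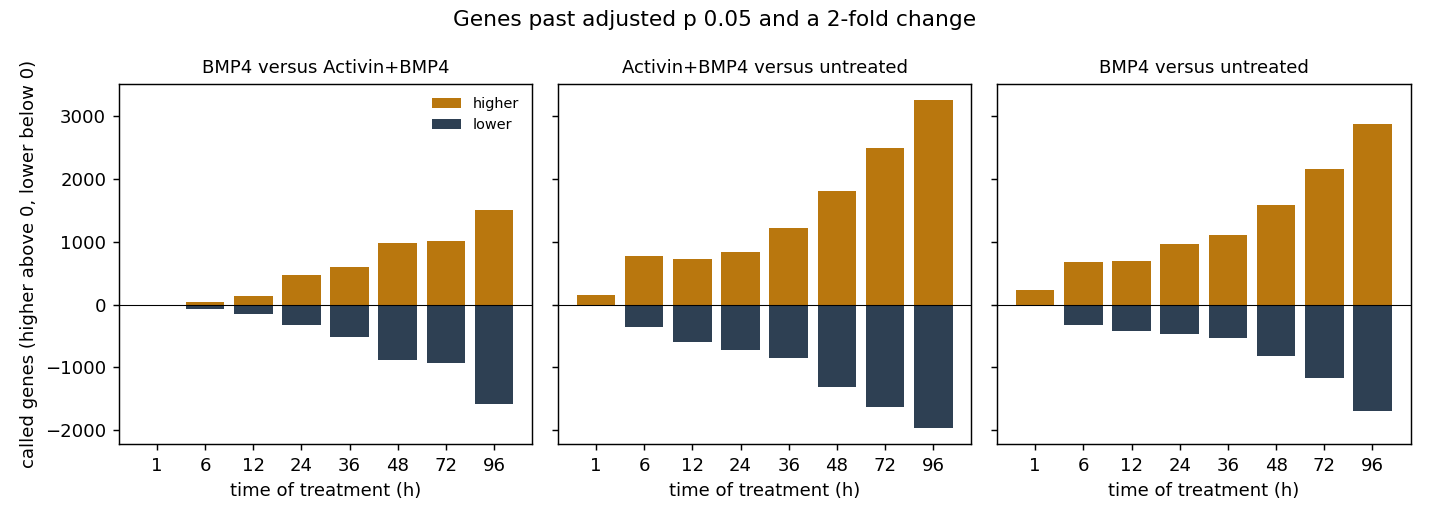
Number of called genes against time of treatment in hours, with bars above 0 for genes higher and bars below 0 for genes lower in the condition named first in each panel title. BMP4 versus Activin+BMP4 reached 1510 higher and 1588 lower genes at 96 h.

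At 1 h the BMP4 and Activin+BMP4 cultures differed in LEFTY1, a secreted inhibitor of NODAL signalling. Its level was 13 ± 0.726 CPM with BMP4 and 27.6 ± 2.07 CPM with Activin+BMP4, a log2 fold change of -1.08 ± 0.13 (SE; edgeR quasi-likelihood adjusted p = 3.59e-06). Untreated cells had 7.42 ± 0.809 CPM. LEFTY1 belongs to the fixed list of Activin and NODAL targets, of which 1 of 17 tested members was called lower, or 2 when adjusted over the list alone (camera adjusted p = 9.79e-11). The amnion list lay higher with BMP4 by camera (adjusted p = 0.00191), although none of its 20 members was called over all genes and 1 was called higher when adjusted over the list alone. The count of 1 gene depends on the test: DESeq2 called 7 and a fit of these 6 libraries alone called 18. Of those calls 85.7% and 66.7% were higher with BMP4, unlike LEFTY1. Of 19603 genes, 967 had an unadjusted edgeR quasi-likelihood p under 0.05. That is about the share this threshold gives without any difference.

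By 6 h, targets of Activin and NODAL had parted between the conditions. LEFTY1 stood at 109 ± 9.14 CPM with Activin+BMP4 and 0.85 ± 0.101 CPM with BMP4, which was 128-fold lower (log2 -7.00 ± 0.18; edgeR quasi-likelihood adjusted p = 1.08e-29). LEFTY2, its neighbouring paralogue, was 18.7-fold lower at 2.8 ± 0.189 against 52.4 ± 1.23 CPM. CER1, a secreted antagonist of NODAL and BMP, was 16.8-fold lower, and the ligand NODAL itself 13.7-fold lower at 2.49 ± 0.116 against 34 ± 2.13 CPM. TMEM63A and MYORG were 3.77-fold and 2.95-fold lower with BMP4. Genes higher with BMP4 included the transcription factor TFAP2A, at 19 ± 0.795 against 4.26 ± 0.986 CPM (log2 2.16 ± 0.15; edgeR quasi-likelihood adjusted p = 2e-14), and IGFBP3, an insulin-like growth factor binding protein, at 27.9 ± 1.85 against 9.8 ± 0.445 CPM. IRX2 (18 ± 1.89 against 8.74 ± 1.39 CPM) and GRHL3 (15.2 ± 0.454 against 7.49 ± 0.994 CPM) lay close to the 2-fold threshold, and each call was lost when some single libraries were left out.

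Among the gene lists at 6 h, 7 of 17 Activin and NODAL targets were lower with BMP4 and none higher (camera adjusted p = 5.31e-118). The primitive streak list had 3 of 18 members lower, or 4 when adjusted over the list alone (camera adjusted p = 2.11e-10), among them MIXL1 at 0.58 ± 0.0237 against 2.83 ± 0.343 CPM. The BMP target list had 3 of 17 members higher, or 4 when adjusted over the list alone (camera adjusted p = 4.53e-16), among them NOG, a secreted BMP antagonist, at 5.07 ± 0.137 against 1.53 ± 0.208 CPM. In the amnion list 3 of 20 members were higher, the same number as when adjusted over the list alone (camera adjusted p = 1.86e-12). The lateral plate and extraembryonic mesoderm list had 3 of 23 members higher, and adjusted over the list alone 3 higher and 1 lower (camera adjusted p = 0.000297). With an estimated correlation its adjusted p was 0.0514. The 3 were HAND1, GATA5 and TBX3, at 1.36 ± 0.0762, 2.47 ± 0.339 and 1.37 ± 0.245 CPM with BMP4.

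At 24 h the primitive streak genes that had come on with Activin+BMP4 were low with BMP4. MIXL1, a homeobox gene of the streak, was at 109 ± 4.24 CPM with Activin+BMP4 and 1.24 ± 0.512 CPM with BMP4, or 88.6-fold lower (log2 -6.47 ± 0.12; edgeR quasi-likelihood adjusted p = 6.99e-36). TBXT, which encodes brachyury, was 32-fold lower at 1.35 ± 0.471 against 43 ± 1.73 CPM. LEFTY2 was 97.5-fold lower, CER1 41.6-fold and LEFTY1 39.9-fold. In the other direction the BMP4 transcript was 6.53-fold higher with BMP4, at 61.1 ± 2.09 against 9.36 ± 0.533 CPM (log2 2.71 ± 0.07; edgeR quasi-likelihood adjusted p = 3.49e-30). RHOBTB3 was 5.74-fold higher, AMER2 6.86-fold, RAI1 5.56-fold and ANKRD1, a target of YAP signalling, 5.02-fold. RAB4B-EGLN2, a readthrough transcript that overlaps RAB4B and EGLN2 on the same strand, was at 10.8 ± 2.15 against 1.03 ± 1.38 CPM and is uncertain, since its reads are shared. Its call was lost without any 1 of several libraries, for example Activin+BMP4 24 h replicate 1, at an edgeR quasi-likelihood adjusted p of 0.112.

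By list at 24 h, 13 of 18 primitive streak genes were lower with BMP4 and none higher, the same count as when adjusted over the list alone (camera adjusted p = 1.63e-75). The Activin and NODAL targets had 11 of 17 members lower (camera adjusted p = 8.49e-97). Of 16 WNT targets 6 were lower, or 7 when adjusted over the list alone (camera adjusted p = 1e-08), among them SP5 at 3.59 ± 0.12 against 38.2 ± 2.27 CPM. Of 17 BMP targets 6 were higher and 1 lower (camera adjusted p = 1.88e-10), with GATA2 at 20.7 ± 0.555 against 5.89 ± 1.11 CPM and TBX3 at 19.4 ± 1.75 against 5.64 ± 0.301 CPM. The amnion list had 6 of 20 members higher and 1 lower (camera adjusted p = 2.27e-13), with TFAP2A at 62.4 ± 2.53 against 18.7 ± 1.78 CPM. The lateral plate and extraembryonic mesoderm list had 5 of 23 higher and 1 lower, or 5 and 2 when adjusted over the list alone (camera adjusted p = 7.48e-07), with HAND1 at 7.62 ± 0.177 against 0.783 ± 0.256 CPM. In the epithelial list CLDN4 and TJP3 were higher of 22 tested (camera adjusted p = 7.17e-06), CLDN4 at 32.2 ± 1.01 against 11.1 ± 1.53 CPM. The mesenchymal list had 3 of 22 members lower, with CDH2 at 62.4 ± 2.84 against 154 ± 5.45 CPM (camera adjusted p = 0.0129, and adjusted p = 0.276 with an estimated correlation). In the pluripotency list NANOG, at 123 ± 0.398 against 279 ± 11.9 CPM, and GDF3 were lower (camera adjusted p = 0.00577, and adjusted p = 0.186 with an estimated correlation).

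At 48 h amnion genes were high with BMP4 and definitive endoderm genes with Activin+BMP4. The hypoxia-inducible factor gene EPAS1 was 76.7-fold higher with BMP4 at 113 ± 3.95 against 1.47 ± 0.0933 CPM (log2 6.26 ± 0.13; edgeR quasi-likelihood adjusted p = 1.83e-34). WNT6 was at 12 ± 1.34 against 0.0506 ± 0.0571 CPM, TCIM at 34.4 ± 2.11 against 0.171 ± 0.115 CPM, CLIC5 at 23.8 ± 0.905 against 0.239 ± 0.129 CPM and SPNS2 at 34.7 ± 2.3 against 0.598 ± 0.186 CPM. PPARG, a nuclear receptor, was at 10.3 ± 0.286 against 0.119 ± 0.0442 CPM. CER1 reached 1490 ± 56.3 CPM with Activin+BMP4 against 47.2 ± 1.26 CPM with BMP4, or 31.6-fold lower with BMP4 (log2 -4.98 ± 0.10; edgeR quasi-likelihood adjusted p = 5.33e-35). LGR5, an R-spondin receptor gene, was 38.4-fold lower, CHL1 29.5-fold, MAMLD1 33.5-fold and ALPK2 26.9-fold. GATA6-AS1 was 47.3-fold lower. Its end overlaps GATA6 on the other strand, and as the strand setting of the counting is not given, reads in that stretch cannot be assigned to either gene.

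By list at 48 h, 19 of 20 amnion genes were higher with BMP4 and none lower (camera adjusted p = 1.91e-52), and 14 of 20 definitive endoderm genes were lower and none higher (camera adjusted p = 2.11e-28), both counts the same as when adjusted over the list alone. SOX17, a transcription factor of endoderm, was at 4.7 ± 0.33 CPM with BMP4 and 102 ± 4.34 CPM with Activin+BMP4, and GATA4 at 1.92 ± 0.175 and 46 ± 2.35 CPM. The primitive streak list had 14 of 18 members lower (camera adjusted p = 6.19e-29), with LHX1 at 6.46 ± 0.339 against 158 ± 8.47 CPM. The nascent and paraxial mesoderm list had 10 of 19 lower and 2 higher (camera adjusted p = 3.89e-06), with APLNR, an apelin receptor, at 23.3 ± 1.93 against 260 ± 8.37 CPM. The mesenchymal list had 11 of 22 lower and 2 higher (camera adjusted p = 4.94e-27), with the collagen gene COL5A1 at 35.9 ± 0.333 against 305 ± 7.85 CPM, and the epithelial list 6 of 22 higher (camera adjusted p = 2.72e-23), with GRHL2 at 104 ± 2.88 against 43.6 ± 1.1 CPM. BMP targets had 8 of 17 members higher and 1 lower (camera adjusted p = 6.7e-10) and Activin and NODAL targets 9 of 17 lower (camera adjusted p = 7.12e-23). In the trophoblast list, of which 13 of 26 members were expressed enough to be tested, 6 were higher and 2 lower (camera adjusted p = 0.00741), and in the lateral plate list 9 of 23 were higher and 4 lower (camera adjusted p = 0.000138), with ISL1 at 31.7 ± 1.31 against 1.74 ± 0.369 CPM. The HOX list, of which 23 of 39 members were tested, had 8 higher and 1 lower (camera adjusted p = 0.00915, and adjusted p = 0.152 with an estimated correlation), and the WNT list 6 of 16 lower and 2 higher (camera adjusted p = 0.000735, and adjusted p = 0.0826 with an estimated correlation).

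At 96 h mesoderm, amnion and HOX genes were high with BMP4, and definitive endoderm genes with Activin+BMP4. COL3A1, a fibrillar collagen gene, was at 446 ± 23.6 CPM with BMP4 and 0.257 ± 0.163 CPM with Activin+BMP4, or 1700-fold higher (log2 10.73 ± 0.15; edgeR quasi-likelihood adjusted p = 2.77e-44). CDX2, a caudal homeobox gene, was at 31.9 ± 4.11 CPM with BMP4 against 1 count over the 3 Activin+BMP4 libraries, a ratio with a 95% counting interval of 487 to 107000. PRRX1 (27.7 ± 5.63 CPM) and HOXB5 (15.2 ± 1.25 CPM) likewise had 1 count with Activin+BMP4, with intervals of 428 to 94200 and 232 to 51200. HOXB5 overlaps HOXB3 on the same strand and is uncertain. DLX2 (13.5 ± 1.49 CPM) and P2RY6 (12.9 ± 1.14 CPM) had 2 counts, with intervals of 158 to 4740 and 152 to 4560. The intervals cover counting error only. In the other direction LEFTY1 was 999-fold lower with BMP4, at 0.564 ± 0.349 against 551 ± 52.7 CPM (log2 -9.96 ± 0.18; edgeR quasi-likelihood adjusted p = 1.42e-36). LEFTY2 was 226-fold lower at 3.13 ± 0.86 against 700 ± 196 CPM. ACSM4 was at 40 ± 3.87 CPM with Activin+BMP4 against 1 count over the BMP4 libraries, a BMP4 to Activin+BMP4 ratio with a counting interval of 7.5e-06 to 0.00165. FOXQ1 was 185-fold lower at 0.343 ± 0.143 against 64.4 ± 34 CPM, the noncoding RNA LINC01467 133-fold lower and the glucose transporter gene SLC5A9 103-fold lower. In Activin+BMP4 replicate 3, the library that stood apart at this time, LEFTY2 was at 474.8 CPM against 829.3 and 797.1 CPM in the other 2.

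By list at 96 h, 17 of 20 definitive endoderm genes were lower with BMP4 and none higher (camera adjusted p = 6.92e-30). FOXA2, a forkhead factor of endoderm, was at 2.64 ± 0.176 against 59.8 ± 4.45 CPM, SOX17 at 10.5 ± 0.813 against 171 ± 16.2 CPM and CER1 at 49.4 ± 5.26 against 2920 ± 438 CPM. Activin and NODAL targets had 11 of 17 lower and 1 higher (camera adjusted p = 2.31e-28). The lateral plate and extraembryonic mesoderm list had 19 of 23 members higher (camera adjusted p = 1.3e-49), with HAND2 at 26.2 ± 1.91 against 0.165 ± 0.117 CPM. The nascent and paraxial mesoderm list had 17 of 19 higher (camera adjusted p = 3.5e-15), with SNAI2, a factor of epithelial to mesenchymal transition, at 76 ± 6.44 against 0.793 ± 0.102 CPM. HOX genes had 20 of the 23 tested of 39 higher (camera adjusted p = 4.15e-18), amnion genes 17 of 20 higher and 1 lower (camera adjusted p = 2.21e-42), and BMP targets 14 of 17 higher (camera adjusted p = 1.53e-28), with MSX1 at 104 ± 8.08 against 0.361 ± 0.0359 CPM. WNT targets had 7 of 16 higher and 3 lower (camera adjusted p = 6.5e-06), with LEF1 at 80.8 ± 1.83 against 0.98 ± 0.267 CPM. Trophoblast genes had 7 of the 13 tested of 26 higher and 1 lower (camera adjusted p = 0.00109). Pluripotency genes had 5 of 24 lower (camera adjusted p = 3.85e-07), with TDGF1, a NODAL co-receptor gene, at 175 ± 5.56 against 829 ± 35 CPM. Primordial germ cell genes had 4 of 13 lower and 2 higher (camera adjusted p = 0.00654), and those lower included SOX17, PRDM1 and KIT. At this time every list count was the same as when adjusted over the list alone, except visceral and yolk sac endoderm.

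The other lists at 96 h were called by camera and lost with an estimated correlation, or were not called. The mesenchymal list had 11 of 22 members higher and 3 lower (camera adjusted p = 0.00166, and adjusted p = 0.179 with an estimated correlation), with TGFBI at 380 ± 39.9 against 6.68 ± 1.89 CPM and the cadherin gene CDH11 at 394 ± 36.7 against 11.3 ± 1.46 CPM. The neural ectoderm list had 13 of 18 higher and 2 lower (camera adjusted p = 0.0164, and adjusted p = 0.323 with an estimated correlation), and the endothelial and blood list 6 of 15 higher and 3 lower (camera adjusted p = 0.0164, and adjusted p = 0.0748 with an estimated correlation). Cell cycle genes had 0 of 26 called (camera adjusted p = 2.18e-05 upward, and adjusted p = 0.054 with an estimated correlation), with TOP2A at 671 ± 6.47 against 553 ± 21.9 CPM. The p53 list had 1 of 17 lower (camera adjusted p = 0.0368, and adjusted p = 0.321 with an estimated correlation). Primitive streak genes went both ways, with 9 of 18 higher and 7 lower (camera adjusted p = 0.151). Their median lay above 0 while the test leaned below it. CDX1 was at 12.1 ± 0.447 against 0.116 ± 0.0362 CPM, and GSC at 0.782 ± 0.0496 against 46.9 ± 7.46 CPM. Visceral and yolk sac endoderm genes had 5 of 18 higher and 7 lower, or 5 and 8 when adjusted over the list alone (camera adjusted p = 0.885), with HNF4A at 1.34 ± 0.214 against 77.8 ± 16.1 CPM and NID2, a basement membrane gene, at 136 ± 15.8 against 2.97 ± 1.75 CPM. The epithelial (4 of 22 higher, camera adjusted p = 0.981), immediate early (6 of 26 higher and 2 lower, 0.59), hypoxia and glycolysis (1 of 21 higher and 4 lower, 0.14), cholesterol synthesis (1 of 21 lower, 0.122), mitochondrially encoded (0 of 13, 0.526) and fate panel (12 of 28 higher and 13 lower, 0.983) lists were not called by camera.

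**Figure D3:**
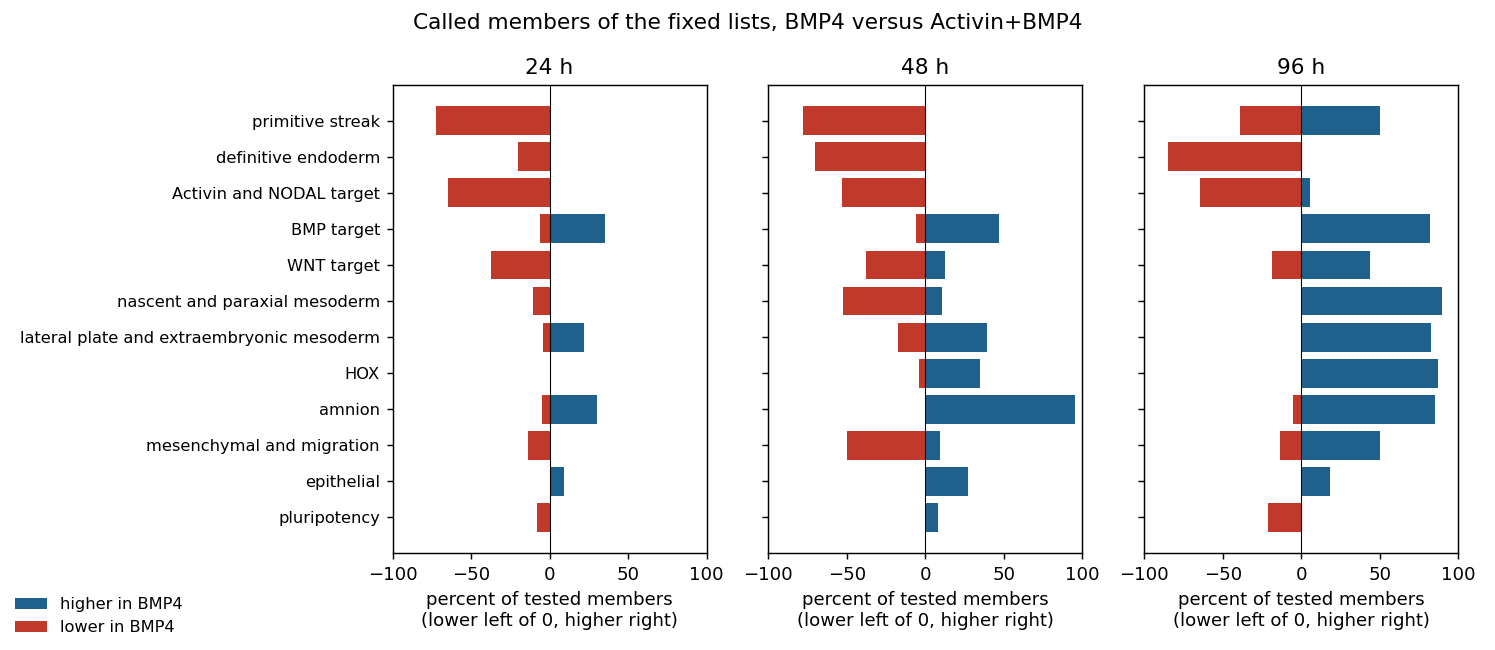
Percent of each list's tested members called higher (right of 0) or lower (left of 0) in BMP4 than in Activin+BMP4 at 24, 48 and 96 h, for 12 lists. Primitive streak genes were 13 of 18 lower at 24 h, amnion genes 19 of 20 higher at 48 h and definitive endoderm genes 17 of 20 lower at 96 h.

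The panel of lineage genes showed when each condition reached its highest measured level. TBXT (chromosome 6, 166157656 to 166168700, minus strand, GRCh38) was highest with Activin+BMP4 at 36 and 48 h, at 113 ± 2.59 and 112 ± 0.626 CPM with overlapping libraries, and with BMP4 at 72 h, at 112 ± 3.34 CPM. MIXL1 (chromosome 1, 226223618 to 226227054, plus strand) peaked at 663 ± 9.59 CPM at 48 h and at 195 ± 10.5 CPM at 72 h, and EOMES was at 527 ± 3.79 CPM at 48 h with Activin+BMP4, overlapped by 478 ± 48.4 CPM at 72 h, and highest at 72 h with BMP4, at 168 ± 11 CPM. SOX17 (chromosome 8, 54457935 to 54460888, plus strand) stood at 168 ± 30.3 CPM at 72 h and 171 ± 16.2 CPM at 96 h with Activin+BMP4, which overlapped, and was highest at 72 h with BMP4, at 14.4 ± 1.64 CPM. HAND1, a bHLH factor of lateral and extraembryonic mesoderm (chromosome 5, 154474972 to 154478264, minus strand), reached 576 ± 49 CPM at 96 h with BMP4 and at most 19.3 ± 0.657 CPM with Activin+BMP4. POU5F1, which encodes OCT4, was not called between the conditions at any time, and at 96 h stood at 633 ± 20.7 CPM with BMP4 and 810 ± 115 CPM with Activin+BMP4 against 1570 ± 54.5 CPM untreated. The 48 h calls of TBXT and SOX2 lay near 2-fold. That of TBXT was lost without BMP4 48 h replicate 3, at a log2 of -0.98, and that of SOX2 without BMP4 48 h replicate 1.

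**Figure D4:**
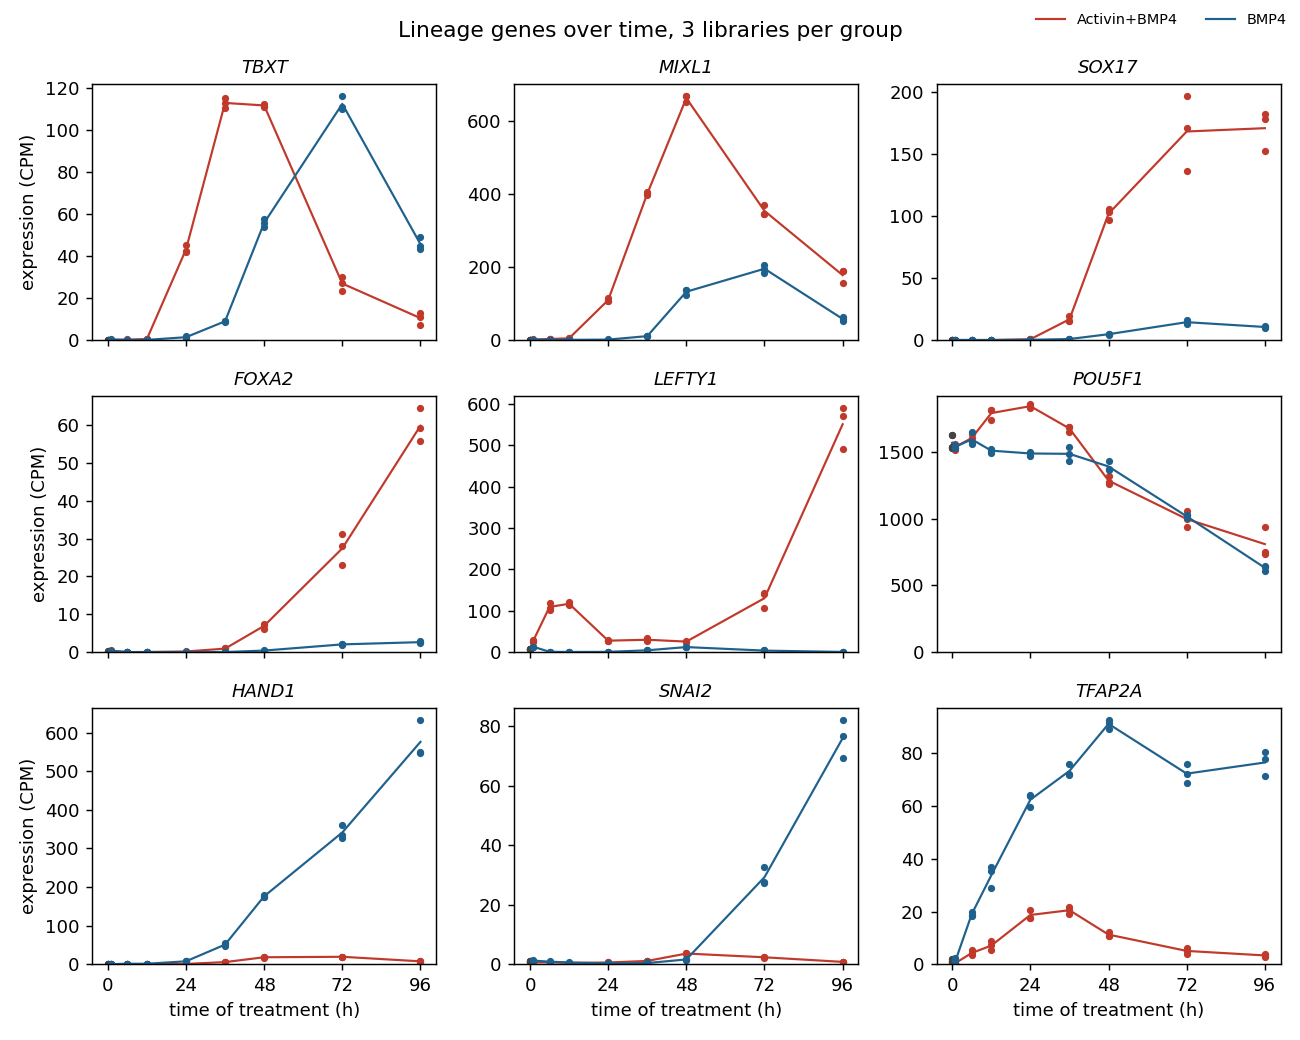
Expression in CPM of 9 lineage genes against time of treatment in hours, on linear axes that start at 0. Points are single libraries and lines join group means, red for Activin+BMP4 and blue for BMP4, both starting from the untreated libraries at 0 h. SOX17 reached 171 CPM with Activin+BMP4 and HAND1 576 CPM with BMP4, each at 96 h.

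Against untreated cells, 181 genes were called after 1 h of Activin+BMP4 (160 higher, 21 lower) and 257 after 1 h of BMP4 (232 higher, 25 lower). Untreated cells were sampled only at 0 h. This comparison and the later ones with untreated cells therefore also hold the change of medium and the time in culture. ARRDC3, an arrestin-domain gene, was at 71.6 ± 3.82 CPM with Activin+BMP4 and 72.6 ± 3.18 CPM with BMP4, against 9.01 ± 1.1 CPM untreated (log2 2.99 ± 0.08 and 3.01 ± 0.08; edgeR quasi-likelihood adjusted p = 4.47e-29 and 3.54e-29). The histone gene H4C14 was at 15 ± 1.71 and 16.6 ± 2.53 CPM against 3.86 ± 2.27 CPM. With Activin+BMP4, GADD45B was 4.28-fold higher at 21.4 ± 1.11 CPM and LEFTY1 3.71-fold higher, and CLK1 and PCDH18 were 2.24-fold and 2.16-fold lower. BMP2 was 2.02-fold lower, a call that some single libraries decided. With BMP4, TXNIP was 3.03-fold higher at 31.7 ± 2.45 CPM, KBTBD11-OT1, which overlaps other genes and is uncertain, was at 12.5 ± 2.9 against 0.402 ± 0.502 CPM, and PCDH18 and CLK1 were both 2.06-fold lower. RN7SL1 (16 ± 4.71 against 84.3 ± 4.15 CPM) and RN7SL2 (19.5 ± 2.84 against 116 ± 5.55 CPM) are near-identical copies, so their values are uncertain, and single libraries ended both calls. BMP targets had 7 of 17 members higher with Activin+BMP4 and 5 of 17 with BMP4. The 257 genes became 143 without BMP4 1 h replicate 1.

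After 24 h of Activin+BMP4, most primitive streak genes were up. In all 1565 genes were called against untreated cells (837 higher, 728 lower). EOMES, a T-box factor, went from 0.668 ± 0.16 to 168 ± 5.52 CPM (251-fold; log2 7.97 ± 0.16; edgeR quasi-likelihood adjusted p = 1.41e-33) and SP5 from 0.136 ± 0.0608 to 38.2 ± 2.27 CPM. EVX1 reached 22.6 ± 1.54 CPM against 1 count untreated, a ratio with a counting interval of 298 to 65800. The noncoding RNA PCAT14 went from 2.14 ± 0.292 to 683 ± 11.6 CPM, 320-fold. The neural genes FEZF1 and HES3 were 7.11-fold and 6.82-fold lower, SORBS2 7.78-fold and CRB2 6.84-fold. By list, 15 of 18 primitive streak genes (camera adjusted p = 2.15e-66), 16 of 17 BMP targets (2.35e-52) and 12 of 17 Activin and NODAL targets (2.16e-50) were higher, the same counts as when adjusted over the list alone. Of 16 WNT targets 10 were higher and 1 lower, or 11 and 1 when adjusted over the list alone (camera adjusted p = 6.32e-20), and 9 of 20 amnion genes were higher and 4 lower (camera adjusted p = 1.85e-10). The p53 list had 4 of 17 members lower, PHLDA3, FAS, SESN2 and GDF15 (camera adjusted p = 2.68e-06). The neural ectoderm list had 6 of 18 lower, with SOX3 at 7.5 ± 0.437 against 26.5 ± 1.45 CPM (camera adjusted p = 0.00553, and adjusted p = 0.253 with an estimated correlation).

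After 96 h of Activin+BMP4, 5224 genes were called (3262 higher, 1962 lower), with genes of endoderm among those higher. FGF17, a fibroblast growth factor gene, was at 611 ± 27.9 CPM against 3 counts untreated, a ratio with a counting interval of 5130 to 72700. GATA4, a zinc-finger factor, was at 188 ± 23.8 CPM against 2 counts, with an interval of 1920 to 57200. The iron exporter gene SLC40A1 was at 43.7 ± 3.09 CPM against 0 counts, at least 1080-fold higher with a floor of 3 counts over the group. GATA6-AS1, at 44.3 ± 4 CPM, was also at least 1080-fold higher. COL12A1 was 41.9-fold lower at 1.11 ± 0.511 against 47.2 ± 1.56 CPM (log2 -5.39 ± 0.17; edgeR quasi-likelihood adjusted p = 1.47e-28), ACTA1 30.1-fold, VGF 29.9-fold and TRBC2 16.9-fold. The definitive endoderm list had 19 of 20 members higher (camera adjusted p = 9.89e-32), the mesenchymal list 15 of 22 higher and 2 lower (1.06e-15), with FN1, fibronectin, at 2960 ± 712 against 192 ± 1.76 CPM, and the visceral and yolk sac endoderm list 11 of 18 higher and 2 lower (2.25e-05), with APOA2 at 17.8 ± 5.32 CPM. Primitive streak genes had 15 of 18 higher and 1 lower (4.15e-18), Activin and NODAL targets 13 of 17 higher and 1 lower (1.24e-20). Pluripotency genes had 12 of 24 lower and 1 higher (1.34e-09), with DNMT3B, a DNA methyltransferase, at 632 ± 33.6 against 2280 ± 22.7 CPM. BMP targets had 9 of 17 higher (6.6e-06, and adjusted p = 0.124 with an estimated correlation), and the cell cycle list 3 of 26 lower (0.00139, and adjusted p = 0.171 with an estimated correlation). These list counts were the same as when adjusted over the list alone.

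After 24 h of BMP4, 1423 genes were called (964 higher, 459 lower), with BMP targets and early amnion genes among those higher. MSX2, a homeobox target of BMP, went from 0.338 ± 0.137 to 47.1 ± 1.59 CPM (137-fold; log2 7.10 ± 0.20; edgeR quasi-likelihood adjusted p = 3.07e-28) and GATA3 from 0.559 ± 0.209 to 53 ± 2.66 CPM. NOG reached 13.2 ± 0.176 CPM and PCAT14 1050 ± 21.5 CPM. JAKMIP2-AS1, which lies over JAKMIP2 on the other strand, was 7.46-fold lower and PRUNE2 6.03-fold lower. RN7SL1 and RN7SL2 were 10.4-fold and 9.69-fold lower, and as near-identical copies are uncertain. The BMP target list had 16 of 17 members higher (camera adjusted p = 5.96e-93), the amnion list 10 of 20 higher (8.56e-34), the lateral plate list 10 of 23 higher and 1 lower (3.61e-11) and the WNT list 7 of 16 higher and 1 lower (6.95e-08). The primitive streak list had 9 of 18 higher and 2 lower (4.97e-07), with EOMES at 14.8 ± 0.709 CPM, and the pluripotency list 1 of 24 lower (6.5e-06), PRDM14 at 46.6 ± 3.36 against 103 ± 1.23 CPM. These counts were the same as when adjusted over the list alone. Activin and NODAL targets had 2 of 17 higher and 3 lower (camera adjusted p = 0.716), with LEFTY1 at 0.686 ± 0.231 against 7.42 ± 0.809 CPM.

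After 96 h of BMP4, 4577 genes were called (2884 higher, 1693 lower), with mesoderm, amnion and HOX genes among those higher. COL3A1 was at 446 ± 23.6 CPM against 0.0553 ± 0.0642 CPM. The proteoglycan gene LUM was at 206 ± 15.1 CPM against 2 counts untreated, a ratio with a counting interval of 2100 to 62600. HOXB6 (44.4 ± 5.48 CPM) and CDX2 (31.9 ± 4.11 CPM) had 0 counts untreated and were at least 1090-fold and 779-fold higher with a floor of 3 counts over the group. HOXB6 overlaps HOXB3 on the same strand and is uncertain. D21S2088E was 29-fold lower at 0.805 ± 0.193 against 23.2 ± 0.557 CPM (log2 -4.86 ± 0.11; edgeR quasi-likelihood adjusted p = 5.36e-33), MYH2 20.7-fold and ARC 17.8-fold. By list, 20 of 20 amnion genes (camera adjusted p = 4.51e-37), 22 of 23 lateral plate and extraembryonic mesoderm genes (2.78e-40), 16 of 19 nascent mesoderm genes (3.71e-14) and 17 of 17 BMP targets (2.39e-37) were higher. The HOX list had 22 of the 23 tested of 39 higher, or 23 when adjusted over the list alone (camera adjusted p = 6.64e-12), and the mesenchymal list 18 of 22 higher and 1 lower (2.47e-31), with ZEB2 at 70.2 ± 6.69 against 1.45 ± 0.466 CPM. Primitive streak (15 of 18 higher, 2.04e-17), trophoblast (11 of the 13 tested of 26 higher, 0.000274) and visceral endoderm genes (14 of 18 higher and 2 lower, 1.71e-06) also rose by camera. Definitive endoderm genes had 13 of 20 higher (1.04e-07), with SOX17 at 10.5 ± 0.813 against 0.0408 ± 0.0402 CPM. Pluripotency genes had 16 of 24 lower (1.3e-27), with NANOG at 46.3 ± 1.33 against 187 ± 2.32 CPM. The p53 list had 4 of 17 lower (0.0021, and adjusted p = 0.122 with an estimated correlation), and mitochondrially encoded genes 8 of 13 lower without a camera call (0.0733). Apart from HOX, these counts were the same as when adjusted over the list alone.

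At 6, 12, 36, 48 and 72 h, 1129, 1328, 2070, 3115 and 4138 genes differed from untreated cells with Activin+BMP4. With BMP4, 1003, 1117, 1654, 2406 and 3335 genes differed.

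The difference between the conditions at 96 h was set against that at 24 h in an interaction test, which called 2645 genes (1105 with a difference shifted towards BMP4, 1540 towards Activin+BMP4). Among genes that met the naming rule, mesoderm and posterior genes shifted most towards BMP4. They were PRRX1, CDX2, COL3A1 (log2 10.34 ± 0.71), CDX1 (9.73 ± 0.31) and HOXB9 (8.66 ± 1.03). For PRRX1 and CDX2 the size of the shift is not given, since Activin+BMP4 at 96 h had 1 count of each. Their place in the order is uncertain for the same reason. CDX2 was at 9.12 ± 0.652 CPM with BMP4 and 7.44 ± 1.24 CPM with Activin+BMP4 at 24 h. SLC5A9 (-6.47 ± 1.3), UPK1B (-6.20 ± 0.63) and RTN4RL1 (-5.90 ± 0.63) shifted towards Activin+BMP4. For RTN4RL1, edgeR's quasi-likelihood adjusted p was 5.9e-11. HNF4A and ACSM4 shifted the same way by an uncertain amount, with 3 counts of HNF4A in each condition at 24 h and at most 1 count of ACSM4 outside Activin+BMP4 at 96 h. Both calls were lost without BMP4 24 h replicate 2, at edgeR quasi-likelihood adjusted p of 0.244 and 1.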

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

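The genes in this part were picked out by their results, after these were seen. The interaction of condition and time was called for 2645 genes, so the difference between the conditions depends on the time, and that is what brought it here. In 90 genes the difference between the conditions was called at both times with opposite signs, 58 of them lower with BMP4 at 24 h and higher at 96 h, and 32 the other way. Groups of 3 libraries were not tested for outlying values.

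The 15 of these genes that belong to a fixed list or fall under the rule for named genes are each given as the log2 difference between the conditions at 24 h, at 96 h and the change between them. TBXT went from -5.00 to 2.13, a change of 7.13 ± 0.19, with 43 CPM at 24 h and 10.4 CPM at 96 h in Activin+BMP4 against 1.35 and 45.6 CPM in BMP4. LEF1 went from -1.58 to 6.36 (7.94 ± 0.18), CDX1 from -3.09 to 6.64 (9.73), SP5 from -3.41 to 1.10 (4.51), NKD1 from -1.09 to 2.00 (3.09) and WNT8A from -2.79 to 3.69 (6.48). EVX1 went from -2.51 to 3.66 (6.16) and FGF4 from -2.19 to 1.33 (3.52). APLNR went from -1.20 to 4.12 (5.32 ± 0.23), FLI1 from -1.41 to 5.30 (6.70) and HEY1 from -1.51 to 3.20 (4.70). SNAI2 went from -1.16 to 6.57 (7.73), and its call at 24 h was lost without the filter and without some single libraries. In the other direction ADM went from 1.31 to -1.53 (-2.85 ± 0.17), RHOBTB3 from 2.52 to -1.46 (-3.99) and RTN4RL1 from 1.62 to -4.28 (-5.90). The sign at 24 h rests on low levels in Activin+BMP4 and BMP4 for RTN4RL1 (0.126 and 0.401 CPM), FLI1 (0.522 and 0.195 CPM) and SNAI2 (0.587 and 0.266 CPM).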

How the results depend on the processing

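The alternatives were fixed ahead of the results, except the fit without the 3 libraries that stood apart, which was chosen after results were seen. No direction of a named gene or of a list test was reversed. With RLE factors, without scaling factors and without the filter all 25 counts of called genes stayed within 1.5 times. The stricter filter, which tests fewer genes, lowered 21 of the 25 by over 1.5 times. For BMP4 versus Activin+BMP4 it gave 513 at 24 h, 714 at 36 h, 1115 at 48 h, 1091 at 72 h and 1805 at 96 h. For Activin+BMP4 versus untreated it gave 74, 625, 794, 966, 1322, 1975, 2581 and 3397 from 1 to 96 h, and for BMP4 versus untreated 106, 532, 626, 839, 995, 1463, 2049 and 2893. BMP4 versus Activin+BMP4 at 1 h went from 1 gene to 18 with only the groups compared and 7 with DESeq2. BMP4 at 1 h versus untreated went from 257 genes to 143 without BMP4 1 h replicate 1 and 276 without replicate 2, and the cause was not tested.

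Replicate number as a block moved no count by over 1.5 times and changed no call of a named gene; 106 list tests were called against 107. An estimated correlation ended 32 of the 216 list results. The fit without the 3 libraries moved no count by over 1.5 times. Named calls near the threshold were lost in single fits: FOXA2 and SNAI2 at 24 h and CXCR4 at 12 h without the filter, TBXT at 48 h without scaling factors and HNF4A in the interaction with only the groups compared. SOX17 at 24 h, TBXT and CXCR4 at 12 h and GATA3 at 72 h were lost without some single libraries.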

Other observations

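The genes in the next 2 paragraphs were picked, and all tests below chosen, after results were seen. HMGCS1, which encodes an early enzyme of cholesterol synthesis, dipped at 6 h in both conditions. It went from 673 ± 18.6 CPM (n = 3) untreated to 305 ± 7.89 CPM with Activin+BMP4 and 329 ± 17.1 CPM with BMP4, and was back at 671 ± 22.6 and 642 ± 11.6 CPM at 24 h. SQLE, of the same pathway, went from 256 ± 4.27 to 156 ± 2.37 and 158 ± 2.8 CPM at 6 h, less than 2-fold and not called. The list as a whole was not tested at this time against untreated cells.

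LHX5 and SIX3, homeobox genes of the forebrain, were higher late with BMP4. LHX5 was at 37.3 ± 7.15 CPM at 72 h and 25.2 ± 4.3 CPM at 96 h against 3.19 ± 1.63 CPM untreated, and SIX3 at 25.4 ± 5.16 and 28.2 ± 5.95 CPM against 0.353 ± 0.227 CPM. FEZF1, at 48.4 ± 7.01 and 35 ± 5.45 CPM against 20.8 ± 1.16 CPM, was called at 72 h and not at 96 h. With Activin+BMP4 PAX6 reached 39.7 ± 7.45 CPM at 96 h and IGFBP5 500 ± 241 CPM, and the glucose transporter gene SLC2A3 2830 ± 499 CPM against 1170 ± 49.9 CPM with BMP4. The noncoding RNA PCAT14 was highest near 24 h and stood at 58.5 ± 21.3 and 259 ± 26.1 CPM at 96 h with Activin+BMP4 and BMP4.

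Definitive endoderm and mesoderm genes parted between the conditions by 96 h, and a slower course with BMP4 was weighed as an explanation. A delay of 24 h is argued against, since 15 of 20 definitive endoderm members were lower at BMP4 96 h than at Activin+BMP4 72 h and none higher (SOX17 10.5 against 168 CPM, log2 -4.00 ± 0.11). A delay of 48 h alone would leave these members at their Activin+BMP4 48 h levels. Against that time 7 of 20 were called lower and 4 higher. The called members departed from those levels, such as SOX17 at 10.5 against 102 CPM (log2 -3.28 ± 0.11) and CER1 at 49.4 against 1490 CPM. Others were not called, such as GATA4 at 51 against 46 CPM. This list alone therefore does not decide on a delay of 48 h. The same course run later, by any delay, is argued against by the mesoderm, amnion and HOX lists. In these, 64 of 82 members were higher at BMP4 96 h than at each of the 8 Activin+BMP4 times. In the primitive streak list 5 of 18 members were higher and 8 lower at BMP4 96 h than at Activin+BMP4 72 h. Against Activin+BMP4 48 h, 4 were higher and 13 lower. TBXT and MIXL1 did reach their highest level later with BMP4, at 72 h, than with Activin+BMP4, at 36 to 48 h. A delay combined with a different course was not tested and is not excluded. The doses of both factors remain confounded.

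LEFTY1 and LEFTY2 fell after 12 h with Activin+BMP4 and rose again by 96 h. LEFTY1 ran 7.42, 27.6, 109, 117, 27.7, 29.9, 25.5, 130 and 551 CPM from 0 to 96 h and LEFTY2 5.12, 9.43, 52.4, 54.6, 28.7, 23.8, 17.7, 35.7 and 700 CPM. From 48 to 96 h the log2 rise was 4.43 ± 0.12 and 5.31 ± 0.13. NODAL ran 10.3, 17.2, 34, 46.2, 148, 207, 156, 46 and 89.8 CPM over the same times. It rose from 12 to 24 h while LEFTY1 and LEFTY2 fell, and like them was higher at 96 h than at 72 h. From 48 to 96 h its log2 change was -0.8 ± 0.1, less than 2-fold. With Activin+BMP4, 174 genes were called as falling from 12 to 48 h and rising from 48 to 96 h. In all 896 were called as falling and 2059 as rising. Both comparisons use the 48 h libraries, so a low estimate there favours both calls. Of the 174 genes, 23 had also risen from 0 to 12 h. Most of these 23 were at low levels, such as RBM46 at 0.36 CPM at 12 h and 0.0776 CPM at 48 h. That all reads of LEFTY2 are a fixed share of those of LEFTY1 is argued against by the ratio of LEFTY2 to LEFTY1. It ran 4.58 times from 0.275 ± 0.00989 at 72 h to 1.26 ± 0.256 at 96 h. A smaller share passing between the copies, beside each gene's own reads, is not excluded. Nor is a division of shared reads that varies between groups. A single library is argued against, as the lowest 96 h library was 18.6 times the highest 48 h library for the gene with the smaller ratio.

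TMEM63A, beside LEFTY1 on the minus strand of chromosome 1, was also higher with Activin+BMP4 than with BMP4, but not in proportion to it. TMEM63A (225845536 to 225882369) lies 3.91 kb from LEFTY1 (225886282 to 225911382). At 12 h TMEM63A was at 106 ± 4.08 CPM with Activin+BMP4 and 14 ± 1.06 CPM with BMP4, and at 96 h at 94.4 and 14.4 CPM, while LEFTY1 with Activin+BMP4 rose from 117 to 551 CPM. Reads running on from LEFTY1 in a fixed share are argued against as the whole of the TMEM63A excess with Activin+BMP4 over BMP4. That excess was 0.145 of the LEFTY1 excess at 96 h and 2.4 at 24 h, a range of 16.5 times. A smaller fixed share, beside a difference in TMEM63A itself, is not excluded. Of 10 tested neighbours within 250 kb 3 were called at 12 h, against 274 of 19591 other genes (1.4%), and a Fisher test of these counts was run and set aside, since the genes had been picked for showing the pattern.

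In Activin+BMP4 96 h replicate 3, set on a line from 72 h (0) to 96 h (1), the library lay at 0.731 against 0.891 and 0.975 for replicates 1 and 2. HNF4A was at 59.45 CPM in it against 84.27 and 89.61 CPM. Tests of why it lay apart were run and are not reported, and the cause is left open.

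Splits of the libraries into other groups of 3 called fewer genes than the real grouping, which was the only 1 of 10 as large in each comparison, and 10 splits are too few for a share under 0.05. In these comparisons every other split mixed libraries of groups that differ, which widens the spread within groups. Low counts in them were set by the design and are no evidence against chance. In fits of the compared groups alone, real counts and the highest other split were 18 and 5 for BMP4 versus Activin+BMP4 at 1 h, 106 and 1 at 6 h, 237 and 2 at 12 h, 687 and 0 at 24 h, 923 and 0 at 36 h, 1559 and 1 at 48 h, 1597 and 0 at 72 h and 2802 and 0 at 96 h. For Activin+BMP4 versus untreated the real counts were 158, 959, 1139, 1289, 1725, 2635, 3455 and 4590, with 0 in every other split. For BMP4 versus untreated they were 283, 852, 921, 1190, 1363, 1965, 2793 and 4013, with at most 1. For the interaction the real 2359 was the largest, 1 of 100 splits, and the highest other had 2110. In that split, and in the next 4 by count (2054 to 2102 genes), the libraries at 96 h stayed in their real groups with the labels exchanged and those at 24 h were mixed, so the whole difference at 96 h was kept.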
